A study of Drosophila melanogaster with 4 samples.

How the data were processed

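Gene expression was measured in samples labelled as heads of male Drosophila melanogaster after 24 h of fasting. Affymetrix Drosophila arrays were hybridised with biotin-labelled total RNA. There were 4 arrays, 1 for each of 4 groups: a wild-type (WT) control, a TORC mutant, a rescue control and a TORC neuronal rescue. Groups were taken from the sample titles. TORC is the coactivator of the transcription factor CREB whose current gene symbol is Crtc, and it is a different protein from the target of rapamycin kinase complex. The labels do not give the genotype of the rescue control, the driver used for the neuronal rescue or the part of Crtc that the mutation removes.

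The deposited values were probe set intensity values on a linear scale, summarised by the authors with MAS5, per the submitters' processing notes. The MAS5 version was not given in the sources used here. All 4 columns had a 2% trimmed mean of 150 in the values themselves, so each array had been scaled to a common level before deposit. The table held 18952 probe sets, of which 183 were control probe sets. Detection calls and scanner images were not used here. The number of arrays limits the precision: with 1 array per group no replicate error exists, and no p-value is given for any difference between groups.

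Signals were scaled to an equal 2% trimmed mean, which left them in effect as deposited. They were then raised to a floor where they lay below it, and log2 transformed. The floor was the median over the 4 arrays of the signal at the 40th percentile of the probe sets that were not controls, which came to 13.85. A fold with a signal at the floor is a lower bound and is written as at least that fold. A gene was called when its signals differed 2-fold or more, a log2 ratio of 1 or beyond in either direction. These calls are differences in size between single arrays.

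Probe sets were named from the platform annotation. Among the 18769 probe sets that were not controls, 13646 had 1 gene symbol, 402 had several and 4721 had none in that annotation. Those with several or no symbols were left unnamed. Of the probe sets with 1 symbol, 13543 matched a RefSeq gene of the Release 6 assembly by Entrez identifier and 103 kept the symbol of the annotation. No symbol changed in that match. No coordinates are given, because the genome build of the array design is not named in the sources used here. The brightest probe set stood for each of 11981 genes, of which 1094 had several probe sets. Probe sets of a gene did not always give equal ratios. Over 480 genes with a pair of probe sets above the floor, the robust SD between probe sets was 0.35 in log2 units for the mutant against the WT control. It was 0.35 over 418 genes for the neuronal rescue against the rescue control.

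The main comparisons were the mutant against the WT control and the neuronal rescue against the rescue control, which share no array. The other 4 pairings of the arrays were computed in the same way, so that 6 comparisons were made in all. The named genes followed a rule. It took Crtc and, for each main comparison, the 12 highest and 12 lowest log2 ratios among called genes with both signals above the floor, with the 3 largest bounds each way. It also took the 10 genes each way that were opposite in the main comparisons, ranked by the smaller of their absolute log2 ratios. It took the 5 highest and 5 lowest genes of each other comparison, and the 4 members of each gene list with the largest absolute log2 ratio in each main comparison. Other list members could be named to show that a list did not move.

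There were 23 gene lists, which covered CREB signalling, stress defence, fasting and hormone signalling, lipid and carbohydrate metabolism, immunity, and basic cell machinery. They also held markers of tissues present in a head or able to contaminate it. A list's median log2 ratio was taken over members with a mean log2 signal above the floor, which 10201 genes passed. It was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Such a percentile describes these arrays and is not a p-value. The groups, comparisons, floor, fold threshold, naming rule and gene lists were fixed before the data were examined. The division of the gonad list into testis, accessory gland, eggshell and yolk parts, and the choice of the flight muscle genes, were made after the values had been seen.

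Calling and list ranking were tested on simulated data built from the WT control signals of all 11981 genes, with noise equal to the spread between probe sets. The changed genes were drawn only from genes more than 3 log2 units above the floor, so calls for dimmer genes were not tested. For the mutant against the WT control, 96% of 50 genes simulated at 3-fold were called in the right direction, as were 10% of 50 genes at 1.5-fold. Of 11781 genes left unchanged, 0.246% were called. They included genes at the floor, where noise below the floor was cut off, which lowers that share. That noise leaves out variation between animals and between RNA preparations.

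Alternatives covered quantile normalization, median centring, the deposited values without rescaling, 4 other settings of the floor, the mean over probe sets, and thresholds of 1.5-fold and 3-fold. A pair of alternatives was added after seeing the data: use of only the genes above the floor in the mutant and rescue control arrays, and centring of each array on the photoreceptor, neuronal and glial lists. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.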

Results

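RNA labelled as from heads of fasted male flies was profiled on 4 arrays. There was 1 each for the WT control, the TORC mutant, the rescue control and the TORC neuronal rescue. Tissue and sex are as the labels give them, and marker genes described below bear on both. No group had a replicate, so every ratio below compares single arrays. The median signal was 36.2 on the WT control array, 19.4 on the mutant array, 20.2 on the rescue control array and 36.9 on the neuronal rescue array. The share of probe sets above the floor was 63.2%, 53.4%, 54.9% and 63.0% in the same order. Across probe sets, log2 signals correlated most closely between the mutant and the rescue control (r = 0.98) and between the WT control and the neuronal rescue (r = 0.97), while the other pairings gave r from 0.90 to 0.93. These correlations are across probe sets, which are not independent replicates.

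Control transcripts split the arrays in another way. Over 12 probe sets for the Bacillus transcripts that are added to RNA before labelling, the geometric mean signal was 77.3 on the WT control array and 76.8 on the mutant array, against 351 on the rescue control array and 261 on the neuronal rescue array. Hybridisation controls gave a ratio of 1.01 between the same pairs of arrays. Each main comparison lies within one of these pairs, and the other 4 comparisons run across them. The 3′ to 5′ signal ratio of Act5C, a measure of RNA integrity, was 3.86 for the WT control, 2.68 for the mutant, 3.77 for the rescue control and 3.70 for the neuronal rescue. In the same order, the ratio was 4.03, 3.12, 3.44 and 4.19 for eIF-4a and 2.02, 1.57, 1.52 and 1.90 for GAPDH, higher in the WT control and neuronal rescue for both, and 1.78, 2.25, 1.88 and 1.99 for a further actin control.

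The targeted gene was examined first. Crtc (Entrez gene 39970) had a signal of 203 in the WT control, 3.8 in the mutant, 6.7 in the rescue control and 37.4 in the neuronal rescue. It was at least 14.7-fold lower in the mutant than in the WT control, and the rescue control also lay below the floor. The neuronal rescue lay at least 2.70-fold above the rescue control and 5.43-fold below the WT control. With the floor at the 60th percentile, all arrays but the WT control lay at the floor and the rescue difference could not be measured. Whether the probe set lies inside the mutated part of the gene, or in the sequence expressed in the neuronal rescue, is not known from the labels.

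Markers of tissues outside the head separated the arrays. The 10 testis genes on the lists, among them the sperm protein genes Mst87F and Mst98Ca and the testis tubulin betaTub85D, had a median signal of 657 in the WT control and 1097 in the neuronal rescue, against 4.3 in the mutant and 8.6 in the rescue control. For 11 genes of the accessory gland and ejaculatory duct, which make seminal fluid proteins such as the sex peptide SP and Acp26Aa, the medians were 561 in the WT control, 642 in the neuronal rescue, 3.5 in the mutant and 4.2 in the rescue control. Over 26 gut digestive enzyme genes, including alphaTry, betaTry and the Jonah protease Jon65Aiv, the median was 124 in the WT control, 43.8 in the neuronal rescue, 19.6 in the rescue control and 1.6 in the mutant. The flight muscle genes followed another order: the thick filament protein gene fln had a signal of 2156 in the WT control, 14.2 in the mutant, 5251 in the rescue control and 359 in the neuronal rescue, and the flight muscle actin Act88F had 3116, 87.4, 6807 and 627. The yolk protein gene Yp1 had signals of 3235, 4617 and 4524 in the WT control, mutant and neuronal rescue, and 17.6 in the rescue control. In the rescue control Yp2 had a signal of 14.8 and Yp3 133, against 2175 and 1508 in the mutant. The arrays with bright male tract genes were also those with the higher 3′ to 5′ ratios of eIF-4a and GAPDH, but Act5C and the further actin control did not split the arrays this way. Eggshell and female germ line genes had medians between 1.8 and 5.2 on all arrays, below the floor.

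**Figure D1:**
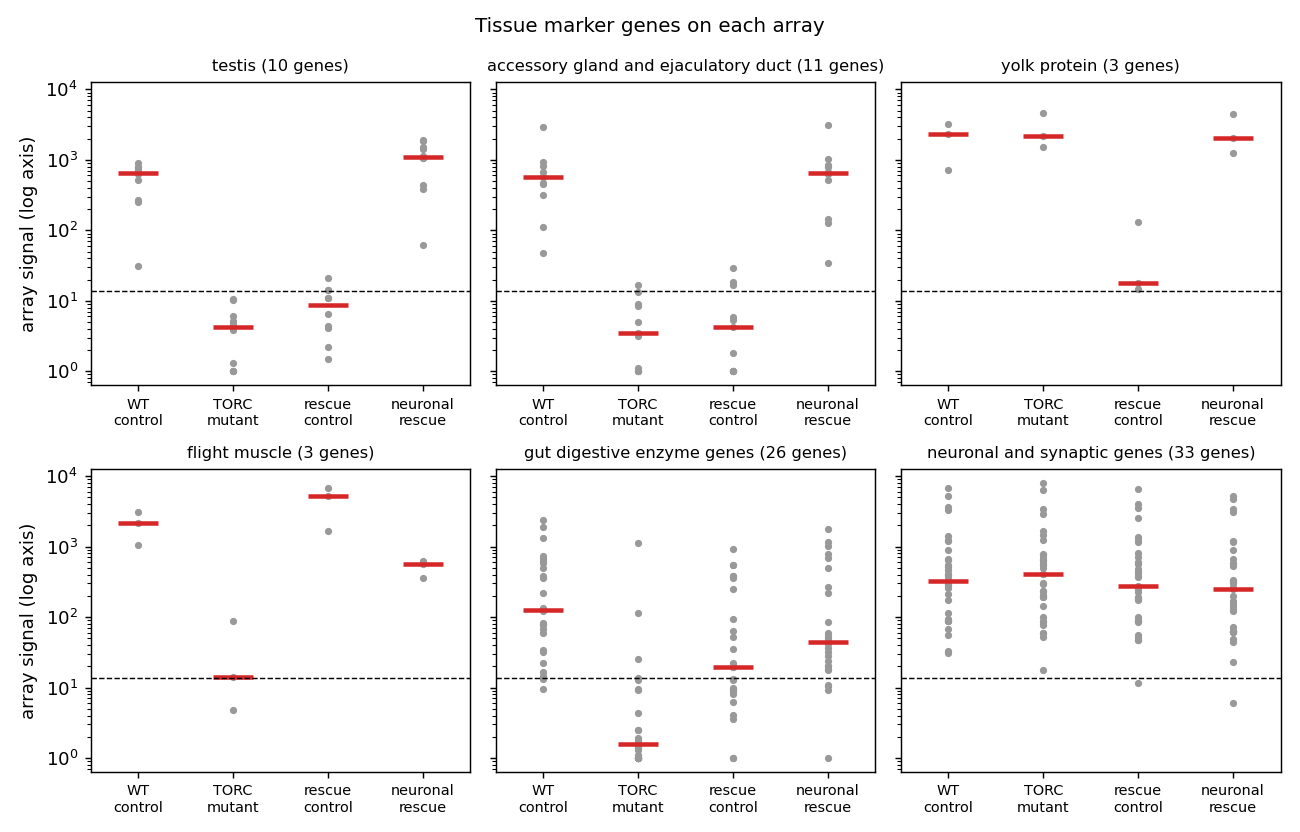
Signals of tissue marker genes on each of the 4 arrays, on a log axis in array signal units. Grey points are genes, red bars are medians, the dashed line is the floor of 13.85, and signals below 1 are drawn at 1. Testis and accessory gland genes lie above the floor on the WT control and neuronal rescue arrays, with medians of 657 and 1097 for testis and 561 and 642 for accessory gland.

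The mutant was compared with the WT control to ask what loss of TORC does to transcripts of the fasted head. Markers of tissues outside the head differed between these arrays, so the ratios alone do not separate loss of TORC from tissue makeup. The highest ratio with both signals above the floor was that of Pepck2, a phosphoenolpyruvate carboxykinase of the kind that feeds gluconeogenesis, with a signal of 49 in the WT control and 3226 in the mutant, 65.8-fold higher. TotC, a secreted stress peptide of the Turandot family, was 18.7-fold higher in the mutant, the cytochrome P450 gene Cyp6a2 11.6-fold, the glycine N-methyltransferase gene Gnmt 11.6-fold and the glucuronosyltransferase gene Ugt35C1 9.21-fold. The larval serum storage protein gene Lsp2 was 7.70-fold higher and the peptide hormone gene CCHa2 7.68-fold. CG6912, CG16704, CG5773, plum and CG31205 completed the 12 highest, at 5.90-fold to 7.53-fold. CG31219, CG11893 and CG4650 were below the floor in the WT control and at least 21.1-fold, 10.9-fold and 9.86-fold higher in the mutant.

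The lowest ratios included flight muscle and seminal protein genes beside genes on none of the tissue lists. CG18628 was 171-fold lower in the mutant, fln 152-fold, CG31740 114-fold and Act88F 35.7-fold. Cyp4g1, a P450 used by oenocytes to make cuticular hydrocarbons, had a signal of 3796 in the WT control, 50.7 in the mutant, 412 in the rescue control and 4984 in the neuronal rescue. The maltase gene Mal-A1 was 28.4-fold lower and the seminal protein gene Acp63F 33.6-fold. CG8701, CG9016, CG31538, CG7768 and Jhbp5 were 17.4-fold to 44.7-fold lower. These genes, with CG18628 and CG31740, were bright on the WT control and neuronal rescue arrays and dim on the others, as the testis genes were. CG18628, for example, had 2675, 15.6, 27.6 and 5635 in the WT control, mutant, rescue control and neuronal rescue. The ejaculatory bulb genes Ebp and EbpII were at least 224-fold and 202-fold lower, and the accessory gland gene Acp98AB at least 210-fold. Of 11981 genes, 208 were at least 2-fold higher in the mutant and 1391 at least 2-fold lower, and the mutant signal was at the floor for 1128 of the latter. With quantile normalization, 602 genes were higher and 1085 lower, and with the floor at the 60th percentile 134 were higher and 378 lower.

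**Figure D2:**
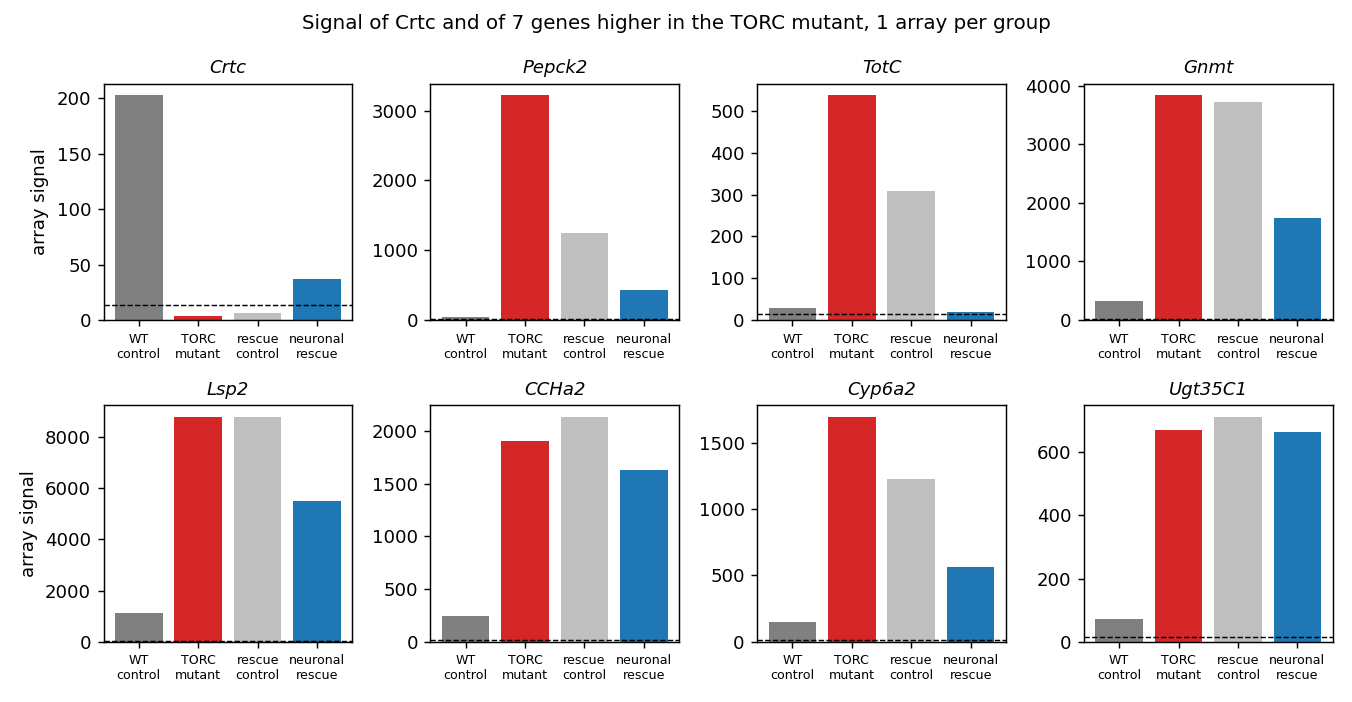
Signal of Crtc and of 7 genes among the highest in the mutant, in array signal units on linear axes that start at 0, with 1 bar per array and a dashed line at the floor of 13.85. The bars for Pepck2 stand at 49, 3226, 1249 and 435 for the WT control, mutant, rescue control and neuronal rescue, and those for Ugt35C1 at 72.7, 669, 712 and 664.

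Among the metabolic lists, the carbohydrate list had 1 of 35 measured members at least 2-fold higher in the mutant, Pepck2, and 8 lower. The lower members were 7 maltase genes and the glucosidase gene tobi (signal 550 in the WT control and 3.3 in the mutant), and the median log2 ratio of the list was -0.08. In the rescue control and neuronal rescue, tobi had 17.0 and 135. The maltase gene Mal-A7 had 200, 5.2, 26.7 and 200 in the WT control, mutant, rescue control and neuronal rescue. Both were thus brighter on the arrays with bright male tract genes. In the lipid list of 31 genes, the lipid droplet protein gene Lsd-1 was the 1 higher member, at a signal of 406 in the WT control and 1658 in the mutant. Its 5 lower members included the gut lipase gene mag (736 and 59.0), the fatty acid synthase genes FASN2 and FASN3 and the carnitine palmitoyltransferase gene whd, and the list median was 0.20. The head fat body list had 6 higher and 2 lower members of 25, with a median of 0.24 at percentile 98.4 of matched random lists. Its higher members included the iron carrier gene Tsf1 (2237 and 5419) and fit (69.1 and 264), a secreted protein gene of the fat body. The starvation and FOXO list had no higher and 3 lower members of 17, namely tobi, ImpL2 and Lip4, with a median of -0.02. Of 28 insulin-like peptide and neuropeptide genes, CCHa2 and the eclosion hormone gene Eh (11.4 and 87.0) were higher and Proc was lower, with a median of 0.10.

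Stress and immune genes went both ways. The oxidative stress list of 29 had 4 members at least 2-fold higher, among them GstE7 (108 in the WT control and 424 in the mutant), the peroxidase gene Pxd (17.3 and 82.6) and the malic enzyme gene Men (2179 and 5214). Another probe set of Pxd had a log2 ratio of 0.59, short of 2-fold. The oxidative stress list also had 4 lower, among them the Nrf2 homologue cnc (702 and 145) and Prx6c (767 and 133), with a median of 0.14. Of 24 antimicrobial and immune effector genes, DptB, Drs, Mtk and PGRP-SB1 were higher, Drsl5 and edin lower, and the median was 0.05. The 6 measured Turandot and JAK-STAT genes included TotC and Stat92E (866 and 2044) as higher members, with a median of 0.32. The CREB list of 16 had no higher member, and Crtc and the early growth response homologue sr were lower, with a median of 0.02. Heat shock and chaperone genes had a median of -0.06 with Hsc70-2 lower (1 of 14). Of 69 P450 genes, 9 were higher and 7 lower, with a median of 0.04.

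For genes typical of the head, the medians were 0.13 for 23 photoreceptor genes (1 higher, Cpr72Ec), 0.07 for 33 neuronal genes (1 higher, the tyrosine hydroxylase gene ple), 0.17 for 19 glial genes (none called) and 0.22 for 9 eye pigment genes (none called). The 16 circadian genes had a median of 0.23, with Pdp1 (815 in the WT control and 251 in the mutant) and Achl lower. The 20 olfactory and gustatory genes had a median of -0.17, with 2 higher and 6 lower. The muscle list had 6 lower of 22 and a median of -0.32, below all matched random lists. The gonad list had 1 higher member, Yp2, and 21 lower of 28, with a median of -5.05, and the gut list 19 lower of 26, with a median of -2.86. In the oxidative phosphorylation list of 69, 15 members were lower and the median was -0.24, below all matched random lists. Against the rescue control, the mutant had a median of -0.17, also below all matched random lists, with 1 member lower. The rescue control had a median of -0.0039 against the WT control, at percentile 9.64. Both of these comparisons cross the split in the added control transcripts. The 15 members lower in the mutant than in the WT control included COX4L, COX7AL and ATPsynCF6L, paralogues of standard subunits. Each of these had a signal under 200 in the WT control and below the floor in the mutant. These were also below the floor in the rescue control, where 3 of 10 testis genes lay above it, and above the floor in the neuronal rescue, as all 10 testis genes were (COX4L 170, 0.9, 1.7 and 331 in the WT control, mutant, rescue control and neuronal rescue). Their log2 ratios of neuronal rescue over WT control were 0.97, 0.99 and 0.95, against a testis median of 0.93. Among the other lower members, ATPsynGL had -0.01 by that ratio, and ND-B8 had a signal of 48.4 in the rescue control. The ribosomal protein list of 34 had 4 lower members, RpL10Aa, RpL27, RpS19b and RpS5b, with a median of 0.08. RpL10Aa (87.2, 2.7, 1.3 and 151), RpS19b and RpS5b split the arrays as the testis genes do, as did Hsc70-2 (100.5, 0.7, 10.9 and 189.5), and RpL27 did not (5858, 2596, 5913 and 6594). The 26 proteasome genes had a median of 0.33 at percentile 99.1, with none called, and the median was 0.16 after centring on the head lists. That centring turned the ribosomal, neuropeptide, CREB and oxidative stress medians below 0 and brought the immune and P450 medians to 0, and quantile normalization turned the ribosomal median below 0. The head list centring also moved the median of genes above the floor on all arrays from 0.07 to -0.10.

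The neuronal rescue was compared with the rescue control to ask what return of TORC to neurons does. Markers of tissues outside the head differed between these arrays too, so the ratios alone do not separate that return from tissue makeup. The 12 highest ratios included yolk and testis genes: Yp1 was 257-fold higher in the neuronal rescue, Yp2 83.5-fold, CG18628 204-fold, the sperm chromatin gene Mst77F 146-fold, Mst84Dc 105-fold and betaTub85D 80.6-fold. CG12699, CG31226, CG31740, CG31820, CG33340 and CG32652 were 84.3-fold to 139-fold higher. These genes and CG18628 were also bright on the WT control array and dim on the mutant array, as the testis genes were. CG13947, EbpII and Acp98AB were below the floor in the rescue control and at least 391-fold, 230-fold and 226-fold higher in the neuronal rescue. In the other direction, TotC had a signal of 307.8 in the rescue control and 18.8 in the neuronal rescue, 16.4-fold lower. The flight muscle genes fln and Act88F were 14.6-fold and 10.9-fold lower, and the serine protease gene CG18180 8.36-fold. The eye development gene eya was 4.68-fold lower, and the antibacterial peptide genes CecB and DptB 4.36-fold and 3.58-fold.

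Kaz-m1, dyw, CG5172, CG10337 and the noncoding alphagamma-element RNA CR32865 were 3.36-fold to 5.61-fold lower. The antennal odorant-binding protein gene Obp83b and the antennal gene Os-C lay below the floor in the neuronal rescue, at least 5.03-fold and 3.66-fold lower, as did Zasp67, at least 3.85-fold. In all, 1538 genes were at least 2-fold higher and 180 at least 2-fold lower, and the rescue control was at the floor for 1244 of the former. Quantile normalization gave 1259 higher and 857 lower, and centring on the head lists gave 1880 and 64.

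Of 24 antimicrobial and immune effector genes, none was at least 2-fold higher and 7 were lower, with a median log2 ratio of -0.52, below all matched random lists. DptB had a signal of 4293 in the rescue control and 1199 in the neuronal rescue, Mtk 7099 and 3454, PGRP-SB1 3004 and 1178, and PGRP-SC2 798 and 319. Centring on the head lists left that median at -0.14. Against the mutant, the neuronal rescue had an immune list median of -0.02, with 3 members higher and none lower. The mutant itself had a median of -0.63 against the rescue control, with 8 lower, so the list was high on the rescue control array. The oxidative stress list had 1 higher and 3 lower members of 29, among them GstS1 (3841 and 1496) and GstD2 (386 and 127), with a median of -0.29 at percentile 0.925, and the median was 0.05 after centring on the head lists. The Turandot list had TotC lower (1 of 6) and a median of -0.42, which was 0.02 with the floor at the 20th percentile. The muscle list had 4 lower of 22 and a median of -0.29, which was 0.05 after centring on the head lists. That centring moved the median of genes above the floor on all arrays from -0.14 to 0.20 in this comparison.

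Neuronal genes had a median of -0.38 at percentile 0.01, with the sodium channel gene para the 1 member of 33 called lower. Glial genes had a median of -0.23 (none of 19 called), photoreceptor genes -0.19 (1 of 23 higher, ninaD), eye pigment genes -0.19 (none of 9 called) and circadian genes -0.28 (1 of 16 higher, Pdf). After centring on the photoreceptor, neuronal and glial lists, the medians were 0.15 for eye pigment and 0.17 for circadian genes. Olfactory genes had a median of -0.11, with 3 of 20 lower. The gonad list had 23 members of 28 higher, the 3 yolk genes among them, with a median of 5.57. The gut list had 11 higher and 1 lower of 26, with a median of 0.40. Carbohydrate genes had 7 higher and 1 lower of 35, with 6 maltase genes and tobi higher, Pepck2 lower and a median of -0.12. Among the higher members, Mal-A7 and tobi were brighter on the WT control and neuronal rescue arrays than on the other arrays.

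The median was -0.11 for lipid genes, with FASN2 and FASN3 higher and Lsd-1 lower (1370 in the rescue control and 617 in the neuronal rescue) among 31. It was -0.12 for 25 fat body genes (4 higher, 1 lower) and -0.13 for 17 starvation genes (tobi higher, ImpL2 lower). Of 28 neuropeptide genes, Pdf and Proc were higher and Akh lower, with a median of -0.05. The CREB list had Crtc higher and the CREB-binding protein gene nej lower among 16, with a median of -0.23. The median was -0.21 for 14 heat shock genes (Hsc70-2 higher) and -0.10 for 69 P450 genes (4 higher, 1 lower). Oxidative phosphorylation genes had 16 higher of 69 and a median of -0.08, ribosomal genes 4 higher of 34 and a median of 0.10, and proteasome genes none called of 26 and a median of -0.15. COX4L, COX7AL, ATPsynCF6L, RpL10Aa, RpS19b and RpS5b, which split the arrays as the testis genes do, were among the higher members here, as was Hsc70-2. FASN2 and FASN3 of the lipid list were also brighter on the WT control and neuronal rescue arrays than on the other arrays. Centring on the head lists moved each negative median given here, and that of the carbohydrate list, above 0, and median centring did so for oxidative phosphorylation genes. The head list centring also moved the median of genes above the floor on all arrays from -0.14 to 0.20. Such a sign change therefore does not set a list apart.

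**Figure D3:**
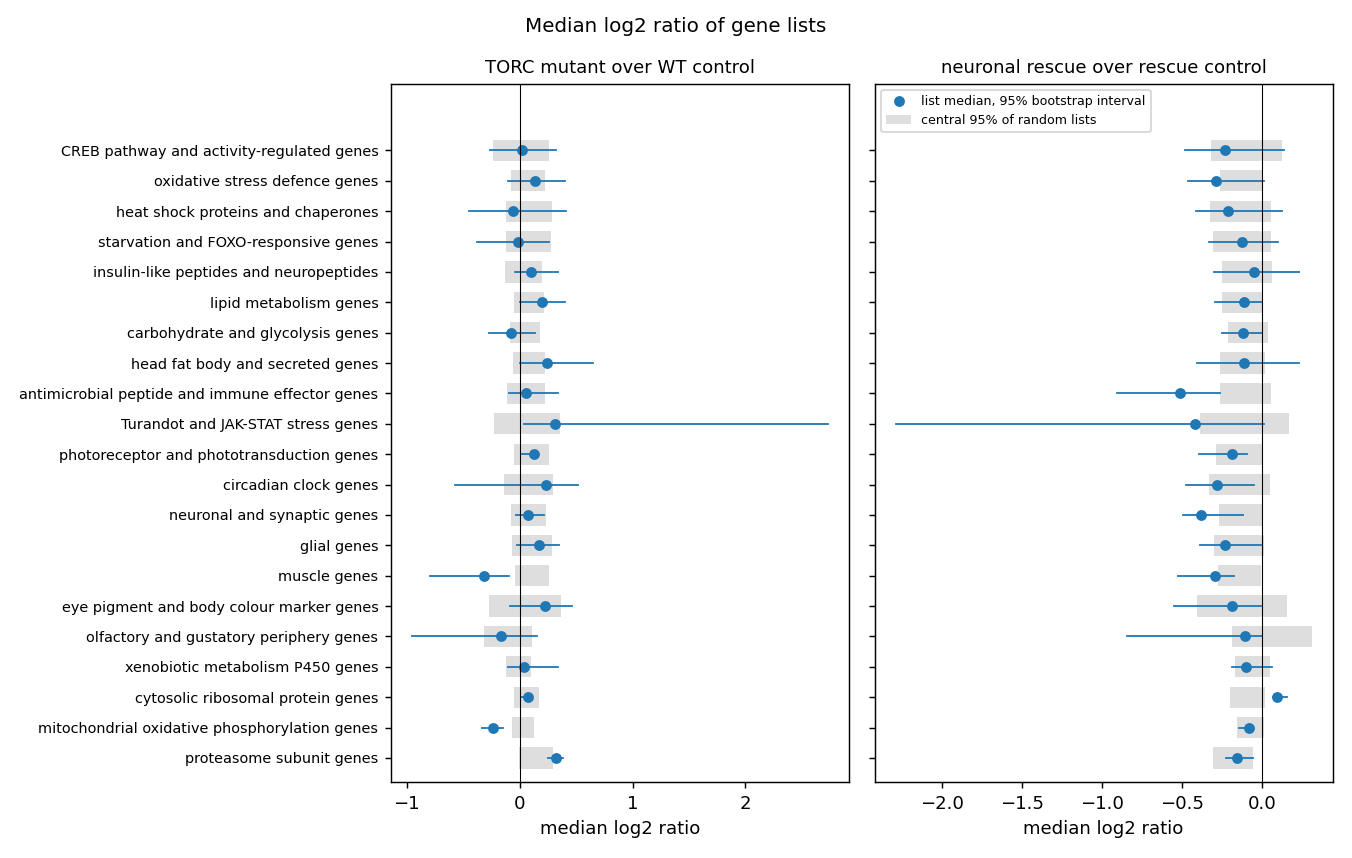
Median log2 ratio of 21 gene lists in each main comparison (points), with the 95% bootstrap interval over genes (lines) and the central 95% of matched random lists (grey bars). The gonad and gut lists are not drawn because their medians in the mutant comparison, -5.05 and -2.86, lie far outside the scale. The immune list has a median of 0.05 on the left and -0.52 on the right.

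The main comparisons were then set against each other, to ask which differences in the mutant were opposite in the neuronal rescue. Of the 208 genes at least 2-fold higher in the mutant than in the WT control, 35 were at least 2-fold lower in the neuronal rescue than in the rescue control and 3 were higher. Random sets matched on expression had a mean of 3.83 lower genes and at most 13. TotC led these genes, followed by CR32865, DptB, the glutathione transferase gene GstD2 (47.3 in the WT control, 139 in the mutant, 386 in the rescue control and 127 in the neuronal rescue), Pepck2, CG30091, CG13056, yellow-d2, CG12483 and the peptidoglycan recognition gene PGRP-SB1. DptB, GstD2, yellow-d2 and PGRP-SB1 were brightest in the rescue control. So were CR32865 (75.0 in the mutant and 116 in the rescue control) and CG30091 (53.4 and 65.4). The log2 ratios of neuronal rescue over mutant for DptB, GstD2, yellow-d2 and PGRP-SB1 were -0.32, -0.13, -0.67 and -0.66. These genes were thus not 2-fold below the mutant. The others named here were. Others of the highest genes in the mutant were not 2-fold lower in the neuronal rescue: Lsp2 had 8793 in the rescue control and 5512 in the neuronal rescue, CCHa2 2138 and 1628, and Ugt35C1 712 and 664. The median log2 ratio of the 208 genes between the neuronal rescue and the rescue control was -0.49, against -0.14 to -0.01 for the central 95% of random sets.

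Of the 1391 genes at least 2-fold lower in the mutant, 1111 were at least 2-fold higher in the neuronal rescue than in the rescue control and 17 were lower. The largest were Ebp, Acp98AB, EbpII, CG18628, CG17376, Mst57Da, Acp53C14b, Acp53C14a, CG31740 and CG12699. Several of these are seminal fluid or ejaculatory bulb genes. Of the 1111 genes, 894 were at the floor in both the mutant and the rescue control. Random sets matched on expression had a mean of 497 higher genes and at most 546. Across the 7492 genes above the floor on all arrays, the log2 ratios of the main comparisons had r = -0.43 and rho = -0.35. The arrays can be matched into a pair of disjoint ratios in other ways, which gave r = -0.23 and r = -0.22. The covariances of these pairings are tied to that of the main comparisons by arithmetic, so they are not an independent reference for it. Genes are not independent replicates.

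**Figure D4:**
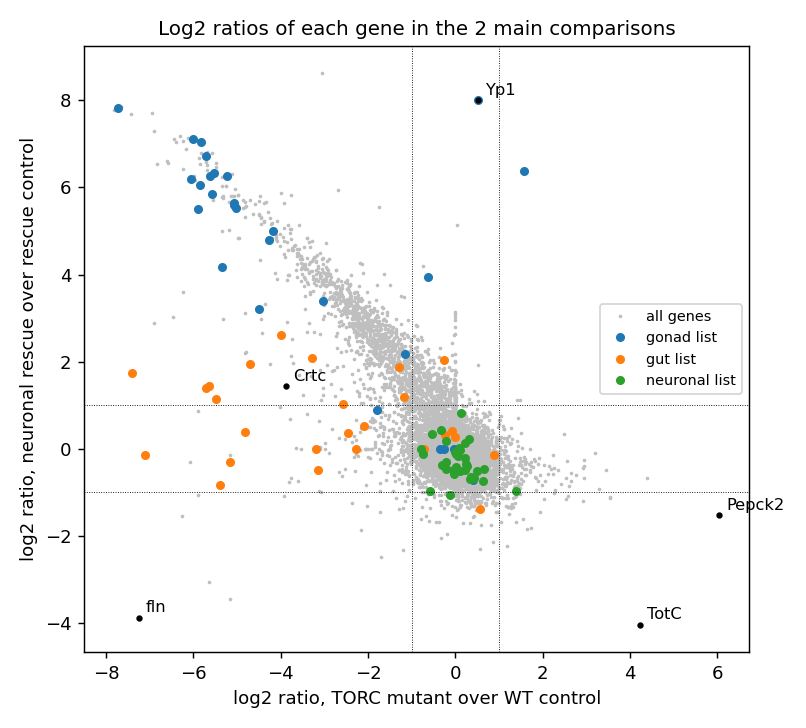
Log2 ratio of each gene in the mutant over the WT control (horizontal) and in the neuronal rescue over the rescue control (vertical), with dotted lines at 2-fold. Gonad list genes (blue) run from upper left, gut genes (orange) lie mostly to the left, and TotC lies at 4.22 and -4.03.

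The remaining comparisons cross the split in the added control transcripts and share arrays with the main ones. The neuronal rescue against the mutant had 1666 genes at least 2-fold higher and 357 lower, which were 1370 and 1020 with quantile normalization and 2481 and 63 with centring on the head lists. CG18628, CG31740, Cyp4g1, CG8701 and CG9016 were 61.2-fold to 361-fold higher in the neuronal rescue, and TotC (28.6-fold), Pepck2 (7.42-fold), eya, CG5172 and Pxd were lower. Another probe set of Pxd had a log2 ratio of -0.23 in this comparison. The rescue control against the WT control had 276 genes higher and 1344 lower. Pepck2 was 25.5-fold higher in the rescue control, Gnmt 11.2-fold, the cold-response gene Fst 10.95-fold, TotC 10.7-fold and Spn88Eb 9.99-fold. Yp1, CG18628, Mst77F, CG12699 and CG31226 were 66.9-fold to 184-fold lower. With quantile normalization 725 genes were higher and 1020 lower.

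The mutant against the rescue control had 99 genes higher and 223 lower, which were 41 and 326 with centring on the head lists and 1041 and 1636 with no floor. Yp1, Yp2 and Yp3 were 262-fold, 147-fold and 11.3-fold higher in the mutant, followed by CG42326 and CG40486. The genes fln (370-fold), Act88F (77.9-fold), CG4783, Mal-A1 (11.6-fold) and CG5506 were lower. The neuronal rescue against the WT control had 636 genes higher and 333 lower. CG13947, Mur29B, CG10912, CG13946 and Fst were 12.8-fold to 47.4-fold higher in the neuronal rescue. CG18180, Drsl4, epsilonTry, CG12374 and the growth factor gene miple1 were 8.86-fold to 24.1-fold lower. Centring on the head lists gave 1540 genes higher and 149 lower in that comparison.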

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

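All tests in this part were chosen after the results they bear on had been seen, and every pattern rests on single arrays. No group had enough arrays to look for one far from the others. A pair of signals appeared in data outside the comparisons. The transcripts added to RNA before labelling were 3.93-fold brighter on the rescue control and neuronal rescue arrays than on the WT control and mutant arrays, with single probe sets from 1.87-fold to 7.05-fold. Among the 4721 probe sets without a gene symbol, 58 were at least 2-fold lower in the mutant than in the WT control, and 38 of them were at least 2-fold higher in the neuronal rescue than in the rescue control.

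The first pattern was the presence of male reproductive tract transcripts on the WT control and neuronal rescue arrays and their near absence from the other pair. Transcription in the head in proportion to the signal of the Crtc probe set is argued against. The median log2 ratio of the 21 tract genes in the neuronal rescue over the WT control was 0.53 (95% bootstrap interval over genes 0.26 to 0.83), where that probe set had -2.44. Whether it measures all the Crtc made in the neuronal rescue is not known from the labels. Proportion to the amount of Crtc itself was therefore not settled. Testis RNA in the WT control and neuronal rescue samples remains a candidate explanation. The log2 ratios of 10 testis genes between these arrays had an SD of 0.21 (interval 0.12 to 0.27), below the 0.44 over all genes above the floor and the 0.31 over genes with signals over 200 on both arrays, as a single source would give, though a gene programme switched on as a unit could give the same. For 11 accessory gland and duct genes the SD was 0.57 (interval 0.25 to 0.77), which leaves a single source open, and a response of any of these genes to Crtc above some level was not tested. Gut enzyme and flight muscle markers also differed between the arrays, and the main comparisons do not separate such differences from those in TORC.

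The second pattern was the yolk protein genes, lower in the rescue control array than in the others, with Yp1 and Yp2 near the floor there and Yp3 at a signal of 133. Less fat body RNA in that sample is argued against, since 22 other fat body genes had a median log2 ratio of -0.09 (interval -0.23 to 0.06) in the rescue control over the mutant, against -7.20 for the yolk genes. Among these 22, Obp99a was also lowest in the rescue control, with signals of 129, 76.6, 4.2 and 254 in the WT control, mutant, rescue control and neuronal rescue. A need of the yolk transcripts for Crtc is also argued against, since the yolk genes had a median of 0.51 in the mutant over the WT control, and the lowest of the 3 had -0.63. Other differences in genotype, and female animals among the other samples, stay open and were not tested. Eggshell and female germ line genes had medians between 1.8 and 5.2 on all arrays, and msl-2, a dosage compensation gene on the gonad list, had signals of 112, 149, 101 and 61.3 in the WT control, mutant, rescue control and neuronal rescue. The list as written also named roX1 and roX2, for which no signals are given here. These values do not settle the sex of the animals. The labels describe all samples as male.

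The third pattern was the set of 208 genes higher in the mutant than in the WT control. Dilution of head RNA by other tissue in the WT control sample is argued against as the whole cause: 75 photoreceptor, neuronal and glial genes had a median log2 ratio of 0.11 (interval 0.02 to 0.17), where the 208 genes had 1.35. Loss of Crtc with a return in the neuronal rescue remains a candidate: in the neuronal rescue over the rescue control, the median of the 208 genes lay -0.24 (interval -0.39 to -0.09) from that of the head lists. That shift is small, and 35 of the 208 genes were 2-fold lower there. Over the WT control, the 208 genes had a median log2 ratio of 0.72 in the neuronal rescue and 1.13 in the rescue control. In the neuronal rescue 75 of them were still at least 2-fold above the WT control, and in the rescue control 126. The genes were chosen with the WT control array, which favours ratios above it. Strain background and the tissue makeup of the samples were not separated from a return of Crtc.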

How the results depend on the processing

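No paired analysis was possible because each group had 1 array and the labels carry no replicate numbers, and for the same reason no array could be left out. The settings with only genes above the floor in the mutant and rescue control, and with centring on the head lists, were chosen after seeing the data. Many signals lay near background: most of the genes lower in the mutant or higher in the neuronal rescue had a signal at the floor, so the height of the floor, by its construction, moves how many were counted, as do the fold threshold and the normalization. Without rescaling, with the mean over probe sets and with median centring, all 13 counts of genes stayed within 1.5 times the values in the report. Over all 12 alternatives, 71 of 156 counts did so and 85 did not. The alternative without rescaling was in effect the main setting, and a 1.5-fold threshold cannot remove a call. Part of the agreement counted here was thus fixed in advance. Of 4648 values for named genes, 4232 kept their side of the threshold, 325 were no longer called, 91 became called and none reversed. Of 456 list medians, 409 stayed within their bootstrap interval. Values outside these limits follow by setting, and except where the floor, the threshold or the choice of genes sets them, the cause was not tested.

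With quantile normalization, genes called were 602 higher in the mutant against WT control, 857 lower in the neuronal rescue against rescue control, 1020 lower in the neuronal rescue against mutant and 725 higher in the rescue control against WT control. The correlation between the main comparisons was -0.56. List medians were -0.024 (ribosomal) and -0.33 (oxidative phosphorylation) in the mutant against WT control and -0.0045 (oxidative phosphorylation) in the neuronal rescue against rescue control. With median centring, list medians were -0.079 (photoreceptor), 0.20 (ribosomal), 0.027 (oxidative phosphorylation) and -0.048 (proteasome) in the neuronal rescue against rescue control.

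With the floor at the 20th percentile, genes called were 478 higher and 2433 lower in the mutant against WT control, 583 lower in the neuronal rescue against rescue control, 2554 higher and 657 lower in the neuronal rescue against mutant, 670 higher and 2281 lower in the rescue control against WT control, 574 higher and 1035 lower in the mutant against rescue control and 1114 higher and 733 lower in the neuronal rescue against WT control. The genes opposite in the main comparisons numbered 1853 and the correlation between the main comparisons was -0.71. List medians were 0.024 (Turandot) in the neuronal rescue against rescue control. With the floor at the 60th percentile, genes called were 134 higher and 378 lower in the mutant against WT control, 540 higher and 79 lower in the neuronal rescue against rescue control, 608 higher and 194 lower in the neuronal rescue against mutant, 168 higher and 357 lower in the rescue control against WT control, 35 higher and 88 lower in the mutant against rescue control and 289 higher and 154 lower in the neuronal rescue against WT control. The genes opposite in the main comparisons numbered 261 and the Crtc log2 ratio was 0 in the neuronal rescue against rescue control. List medians were 3.88 (gonad) in the neuronal rescue against rescue control. With the floor from gonad and gut probe sets, genes called were 30 higher and 22 lower in the mutant against WT control, 29 higher and 9 lower in the neuronal rescue against rescue control, 33 higher and 21 lower in the neuronal rescue against mutant, 33 higher and 19 lower in the rescue control against WT control, 6 higher and 14 lower in the mutant against rescue control and 24 higher and 9 lower in the neuronal rescue against WT control. The genes opposite in the main comparisons numbered 13, the correlation between the main comparisons was -0.32, the Crtc log2 ratio was 0 in both main comparisons. List medians were 0 (gonad), -0.76 (gut), 0.53 (olfactory), -0.13 (P450) and 0.0050 (proteasome) in the mutant against WT control and -0.032 (circadian), -0.10 (neuronal), 0.66 (gonad), 0.17 (olfactory) and -0.15 (oxidative phosphorylation) in the neuronal rescue against rescue control. Without a floor, genes called were 723 higher and 2756 lower in the mutant against WT control, 2549 higher and 801 lower in the neuronal rescue against rescue control, 2851 higher and 888 lower in the neuronal rescue against mutant, 912 higher and 2563 lower in the rescue control against WT control, 1041 higher and 1636 lower in the mutant against rescue control and 1354 higher and 950 lower in the neuronal rescue against WT control. The genes opposite in the main comparisons numbered 2107 and the correlation between the main comparisons was -0.68. List medians were -5.40 (gut) in the mutant against WT control and 0.024 (Turandot) in the neuronal rescue against rescue control.

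At a 1.5-fold threshold, genes called were 793 higher in the mutant against WT control, 958 lower in the neuronal rescue against rescue control, 1313 lower in the neuronal rescue against mutant, 845 higher and 2063 lower in the rescue control against WT control, 525 higher and 643 lower in the mutant against rescue control and 1610 higher and 979 lower in the neuronal rescue against WT control. At a 3-fold threshold, genes called were 61 higher in the mutant against WT control, 25 lower in the neuronal rescue against rescue control, 50 lower in the neuronal rescue against mutant, 89 higher and 859 lower in the rescue control against WT control, 12 higher and 101 lower in the mutant against rescue control and 122 higher and 94 lower in the neuronal rescue against WT control. With only genes above the floor in the mutant and rescue control, genes called were 239 lower in the mutant against WT control, 148 higher in the neuronal rescue against rescue control, 223 higher in the neuronal rescue against mutant, 238 lower in the rescue control against WT control, 115 lower in the mutant against rescue control and 158 higher in the neuronal rescue against WT control. The genes opposite in the main comparisons numbered 105. List medians were 0.41 (gonad) and 0.56 (gut) in the mutant against WT control and -0.13 (gut) and -0.15 (oxidative phosphorylation) in the neuronal rescue against rescue control. Genes at the floor in the mutant are left out by this setting. Only 3 of 26 gut genes and 1 of 11 accessory gland genes lay above the floor there. The gonad and gut medians therefore cover a remainder of those lists. With centring on the head lists, genes called were 64 lower in the neuronal rescue against rescue control, 63 lower in the neuronal rescue against mutant, 41 higher in the mutant against rescue control and 1540 higher and 149 lower in the neuronal rescue against WT control. List medians were -0.064 (neuropeptide), -0.043 (photoreceptor), -0.094 (neuronal), -0.074 (ribosomal), -0.38 (oxidative phosphorylation) and 0.16 (proteasome) in the mutant against WT control and 0.052 (oxidative stress), 0.21 (starvation), 0.27 (neuropeptide), 0.20 (lipid), 0.20 (carbohydrate), -0.14 (immune), 0.15 (photoreceptor), 0.17 (circadian), -0.042 (neuronal), 0.11 (glial), 0.046 (muscle), 0.15 (eye pigment), 0.23 (P450), 0.43 (ribosomal), 0.26 (oxidative phosphorylation) and 0.18 (proteasome) in the neuronal rescue against rescue control. The photoreceptor, neuronal and glial lists lie near 0 here because the arrays were centred on them.

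Quantile normalization moved the median log2 ratio of genes above the floor on all arrays by 0.11 in the mutant against WT control, -0.11 in the neuronal rescue against rescue control, -0.14 in the neuronal rescue against mutant and 0.10 in the rescue control against WT control. It moved the share of lower genes among those called from 87.0% to 64.3%, from 10.5% to 40.5%, from 17.6% to 42.7% and from 83.0% to 58.5% in these comparisons. Median centring moved that median by 0.11 in both comparisons of the neuronal rescue with the rescue control and the mutant. Centring on the head lists moved it by -0.17 in the mutant against WT control, 0.34 in the neuronal rescue against rescue control, 0.57 in the neuronal rescue against mutant, -0.23 in the mutant against rescue control and 0.40 in the neuronal rescue against WT control. It moved the share of lower genes from 17.6% to 2.48%, from 69.3% to 88.8% and from 34.4% to 8.82% in the last 3 of these. The floor from gonad and gut probe sets came to 783, because those genes were bright on the WT control and neuronal rescue arrays, and left 712 genes above it on all arrays, so it was no measure of background.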

Other observations

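Some genes set the WT control array apart from all others. The growth factor gene miple1 had a signal of 1482 in the WT control, 167 in the mutant, 161 in the rescue control and 167 in the neuronal rescue. The drosomycin-like gene Drsl4 had 423, 49.9, 52.0 and 26.3, the P450 gene Cyp4p1 1051, 216, 245 and 224, and the peroxiredoxin gene Prx6c 767, 133, 130 and 94.3. The clock gene Pdp1 had 815, 251, 241 and 234. In the other direction, the P450 gene Cyp12a4 had 118, 667, 600 and 754. These genes were chosen after their values had been seen.

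Against each other array, the median ratio of the immune list was in favour of the rescue control. Of 24 antimicrobial and immune effector genes, 10 were at least 2-fold higher and 1 lower in the rescue control than in the WT control, with a median log2 ratio of 0.86. In the mutant against the rescue control, none was higher and 8 were lower, with a median of -0.63. CecB had signals of 21.1, 38.6, 146 and 33.5 in the WT control, mutant, rescue control and neuronal rescue. Heat shock and chaperone genes had a median of -0.46 in the mutant against the rescue control and 0.36 in the neuronal rescue against the WT control. These comparisons cross the split in the added control transcripts.

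The antennal genes Obp83b, Os-C and a10, chosen after their values had been seen, were lowest in the neuronal rescue. Obp83b had signals of 187, 81.5, 69.7 and 11.5 in the WT control, mutant, rescue control and neuronal rescue, Os-C had 137, 30.6, 50.7 and 10.2, and a10 had 119, 78.5, 84.7 and 27.1. Of 20 olfactory and gustatory genes, 9 were at least 2-fold lower and none higher in the neuronal rescue than in the WT control, with a median log2 ratio of -0.64. Other head lists were also below 0 in that comparison, with medians of -0.53 for 33 neuronal genes (none higher, 6 lower), -0.38 for 19 glial genes and -0.22 for 23 photoreceptor genes. Against the rescue control, 3 of the 20 were lower, with a median of -0.11, and Obp56a was lowest in the WT control (17.2, 84.3, 64.8 and 33.7). The neuropeptide gene Pdf had signals of 435, 220, 187 and 394 in the same order.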
